A study of Mus musculus with 4 samples.

How the data were processed

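Ribosome profiling, which sequences the mRNA fragments protected by ribosomes, was carried out on mouse hearts taken on day 15 after birth. The labels give 4 libraries in 2 groups: 2 libraries from control hearts, WT in the titles and FF in the library names, and 2 from hearts of a conditional knockout of Nat10, called KO. The groups are called WT and KO here. Per the labels' protocols, about 100 mg of heart tissue was frozen, translating ribosomes were held in place with cycloheximide at 100 µg/mL, the lysate was digested with RNase I, ribosomal RNA was depleted, and the footprints were made into libraries with a small RNA kit. The labels name the heart as the tissue and cardiomyocytes as the cell type. The protocols describe whole tissue, so markers of other cell types were followed too. All libraries carry one batch label. The replicate numbers are not said to mark separate animals, so the p-values measure only the spread between these libraries, which may be technical.

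The first deposited table holds footprint levels in FPKM (fragments scaled by gene length and by the mapped total of the library) as made by the authors, with 1 value per Ensembl gene and library for 55382 genes. The second deposited table holds the translation efficiency (TE), a ratio made by the authors. Per the submitters' processing notes, cutadapt 3.7, FastQC 0.11.9, Bowtie 1.3.1, STAR 2.7.4a, HTSeq 0.13.5 and Cufflinks 2.2.1 were used with the GRCm38 (mm10) mouse genome. Their order and settings, the filters on read length and the strand setting are not given in the sources used here. Whether footprints were counted over coding sequence or over whole exons is likewise not given in the sources used here. Reads that map to several near-identical genes may have been split or dropped, which makes values of ribosomal protein genes, histones, globins and genes with many pseudogenes uncertain.

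Dividing each FPKM by the TE of the same gene and library gave a number of at most 6 significant digits in 59296 of 59296 quotients (100%, relative tolerance 1e-10), as a second table printed to that precision would. The quotient was therefore used as the RNA level in FPKM that formed the denominator, and is called the implied RNA level. How the RNA libraries were made, and whether they came from the same hearts, is not given in the sources used here. A TE of 0 stands beside a footprint level above 0 for 1516 to 1987 genes per library, so a TE of 0 was taken as missing.

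The depth of each library is unknown in reads, because FPKM keeps no read total and whole reads could not be recovered. The most common gene-by-gene ratio of low FPKM values, those above 0 and below 1 in both libraries, was taken between libraries. It grows as a library gets shallower, and also where weak genes truly read higher. It was 1.66 for KO replicate 1 over WT replicate 1 (range over resampled genes 1.55 to 1.72) and 1.88 for KO replicate 2 (range 0.96 to 2.00). It was 1.13 for WT replicate 2 over WT replicate 1. Over WT replicate 2 it was 1.36 for KO replicate 1 (range 1.27 to 1.46) and 1.55 for KO replicate 2 (range 1.32 to 2.19). Values of weakly translated genes may therefore rest on fewer footprints in KO, though the range for KO replicate 2 over WT replicate 1 includes no difference. Tested genes of mean FPKM 1 to 10, without small RNA genes and unnamed models, had a median log2 change of 0.438. The ratio therefore cannot tell depth from level. An FPKM of exactly 0 can be a failed estimate: 5 of the 13 protein genes of the mitochondrial genome were listed at 0 in all 4 libraries. Genes at 0 are described only as listed at 0.

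Genes with an FPKM of at least 1 in at least 2 of the 4 libraries were tested (15031 genes). Footprint levels were compared as log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, two-sided, without covariates. Fold changes are on that scale, which understates the change of low genes. TE was compared as log2(TE) in the same way for the 12529 genes that also had a TE above 0 in all 4 libraries, and the implied RNA level as log2 of the quotient for the same genes. An interaction model over both kinds of library was not used, since no counts entered the comparison. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. With 2 libraries against 2, an exact permutation test of a single value cannot go below p = 0.333, so only the model that shares the spread between genes was used.

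Before the data were examined, 30 gene lists were written (919 entries, of which 889 were found by symbol in the tables), together with the tests, most of the alternatives and the rule for naming genes. Lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The lists cover the sarcomere, fetal and stress genes of the heart, ion handling, energy metabolism, ribosomes and translation, stress responses, the cell cycle, histones, extracellular matrix, interferon response, cell death, chaperones, and markers of fibroblasts, endothelium, mural cells, macrophages, lymphocytes, erythroid cells, the atria, epicardium with glia and fat, and skeletal muscle with lung and thymus. Extending the list test to the implied RNA level was decided after the data were examined.

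Genes were named by rule. Nat10 came first. Then came, among named genes past the threshold with a mean FPKM of at least 5 in 1 group and both KO libraries on the same side of both WT libraries, the 12 with the largest rise and the 12 with the largest fall. Unnamed gene models, pseudogenes and small RNA genes were left out. Where fewer than 6 genes of a direction passed, the 6 with the smallest p were given with values only. Up to 4 members of a list were named, those with the smallest p and a mean FPKM of at least 1 in 1 group. The same rule was applied to the implied RNA level after the data were examined. Coordinates and biotypes came from the RefSeq annotation of GRCm38 by symbol, and 14359 of the 15031 tested genes had a symbol found there. Among tested genes, 43 had a symbol that stands on more than 1 Ensembl gene.

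Each comparison was repeated with other pseudocounts, filters, scalings, variance models, thresholds and effect sizes, with the replicate number as a block, with small RNA genes left out, and with each library left out in turn. Tables were joined in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

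The procedure was tested on simulated data with 50 genes changed at each of 4 fold sizes. For footprints it recovered 2% of genes changed 2-fold, 28% at 4-fold, 64% at 8-fold and 72% at 16-fold, with 8 false calls among 14831 unchanged genes. For TE it recovered 2% at 2-fold, 14% at 4-fold, 58% at 8-fold and 90% at 16-fold, with 11 false calls among 12329. For the implied RNA level it recovered 40% at 2-fold, 90% at 4-fold, 94% at 8-fold and 98% at 16-fold, with 15 false calls. The 8 false footprint calls stood beside 1, 14, 32 and 36 recovered genes at the 4 fold sizes in rising order. The 11 for TE stood beside 1, 7, 29 and 45, and the 15 for RNA beside 20, 45, 47 and 49. The noise was drawn for each gene alone from the fitted spread, so genes did not vary together as those of real libraries can.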

Results

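Footprint levels and translation efficiencies were measured in hearts of 15-day-old mice to find the ribosome-protected mRNAs that depend on NAT10, an enzyme that acetylates cytidines in RNA and takes part in ribosome assembly. The series holds 2 WT and 2 KO libraries, and each gives an FPKM and a TE per gene. Between 16425 and 16900 genes had a footprint level above 0 per library. The summed FPKM ran from 7.04e+06 to 8.73e+06, and 48.9% to 57.0% of it lay in tRNA genes of the mitochondrial genome. The median FPKM of the tested genes was 20.4 and 17.3 in the WT libraries and 23.3 and 28.7 in the KO libraries. Across genes, log2 footprint levels correlated at r = 0.93 between the WT libraries, 0.92 between the KO libraries and 0.89 to 0.91 between groups. The implied RNA level correlated at 0.98, 0.96 and 0.89 to 0.94 in the same order. Genes are not independent replicates, so no p-value goes with these correlations.

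The targeted gene was read first. Nat10 (ENSMUSG00000027185), a protein-coding gene on chromosome 2 from 103721258 to 103762954 in GRCm38, had 77.3 and 73.9 FPKM of footprints in the WT libraries and 40.01 and 52.1 in the KO libraries, or 75.6 ± 2.4 against 46.0 ± 8.5 (SD, n = 2). The log2 difference was -0.71 (SE 0.30) and did not pass limma's test (adjusted p = 0.295). Its implied RNA level was 7.02 and 8.34 FPKM in WT and 5.62 and 6.69 in KO (log2 difference -0.32, SE 0.25, adjusted p = 0.424). Its TE was 11.02 and 8.86 in WT and 7.12 and 7.78 in KO (log2 difference -0.41, SE 0.42, adjusted p = 0.915). Both KO libraries lay below both WT libraries in all 3 measures. Such separation, in either direction, was common: 51.65% of tested genes had it for footprints, 62.81% for RNA and 35.93% for TE. TE is made from the other measures, so the 3 are not independent. Which exons the knockout removes is not given in the sources used here, and reads over the remaining exons or from cells that keep the gene would count towards these values.

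The footprint comparison asks which mRNAs gained or lost ribosome-protected fragments in the KO hearts. Among the 17 named genes that rose, Nppa, Gdf15 and Ano3 had the largest rises. Nppa, the atrial natriuretic peptide precursor, rose 45.02-fold, from 894 ± 466 to 42945 ± 29659 FPKM (SD, n = 2, adjusted p = 0.041). Its log2 change of 5.49 was 6.26 without KO replicate 1 and 4.72 without KO replicate 2, and that of Cdkn1a, 4.39, was 4.98 and 3.79. Gdf15, a secreted stress cytokine, rose 44.6-fold, from 3.07 ± 0.24 to 190 ± 85.7 FPKM (adjusted p = 0.014). Cdkn1a, the cell-cycle inhibitor p21, rose 20.9-fold, from 38.6 ± 0.15 to 896 ± 493 FPKM (adjusted p = 0.022), and Eda2r, a receptor of the tumour necrosis factor receptor family, rose 10.97-fold (adjusted p = 0.022). Ddit3, which codes for the stress transcription factor CHOP, rose 22.2-fold on ENSMUSG00000116429 (adjusted p = 0.0043). The symbol Ddit3 stands on 2 Ensembl genes, and their summed FPKM was 27.4 and 34.7 in WT and 591 and 607 in KO. The other gene read 4.04 and 7.12 FPKM in WT and 16.9 and 9.47 in KO and did not pass limma's test (adjusted p = 0.356). Only that other gene has an implied RNA level, which was 2.72-fold higher in KO. How these 2 Ensembl genes relate was not checked, and how reads were shared between them is not given. The size of the Ddit3 rise is therefore uncertain.

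Members of the extracellular matrix list also rose. Ccn2, a matricellular growth factor, rose 14.5-fold, from 252 ± 1.3 to 3996 ± 2255 FPKM (adjusted p = 0.037), and its log2 change of 3.86 was 4.47 without KO replicate 1 and 3.25 without KO replicate 2. Cthrc1, a collagen-associated secreted protein, rose 9.87-fold (adjusted p = 0.015), and Thbs1, the matrix glycoprotein thrombospondin, rose 5.89-fold (adjusted p = 0.041). Eln, elastin, rose 6.70-fold, from 982 ± 22.5 to 6579 ± 55.5 FPKM (adjusted p = 0.010). Outside that list, Ano3, a member of the anoctamin membrane protein family, rose 32.0-fold, from 1.35 ± 0.53 to 73.8 ± 14.0 FPKM (adjusted p = 0.022). Lrrc28, a leucine-rich repeat protein, and Ifrd1, a transcriptional co-regulator, rose 7.59-fold and 7.20-fold (adjusted p = 0.041 for both). The other 5 named risers, listed after their values were seen, were Casq1, Tagln, Fstl1, S100a6 and Bgn, at 5.26-, 4.97-, 4.34-, 3.72- and 3.45-fold (adjusted p = 0.041 for Tagln and Bgn).

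The 5 named genes that fell were Cpt2, Mlf1, Adhfe1, Asb15 and Nnt. Cpt2, the inner-membrane carnitine palmitoyltransferase of fatty acid oxidation, was 3.80-fold lower in KO, at 285 ± 33.0 against 1084 ± 90.2 FPKM (SD, n = 2, adjusted p = 0.041). Adhfe1, a mitochondrial hydroxyacid-oxoacid transhydrogenase, was 4.66-fold lower, Mlf1, myeloid leukaemia factor, 3.84-fold lower, and Asb15, a muscle-enriched subunit of ubiquitin ligases, 6.33-fold lower (adjusted p = 0.041 for each). Rxrg, a retinoid X receptor, read 140 and 155 FPKM in WT and 33.3 and 29.3 in KO and did not pass (adjusted p = 0.057). Nnt, the mitochondrial transhydrogenase, passed on ENSMUSG00000025453 (adjusted p = 0.047), with 21.9 and 50.5 FPKM in WT and 0.011 and 0.021 in KO, and its log2 change of -5.08 was -5.66 without WT replicate 1 and -4.49 without WT replicate 2. The symbol Nnt also stands on ENSMUSG00000116207, which read 1043 and 1053 FPKM in WT and 781 and 1028 in KO. The sum of both genes was 0.83 times the WT level, so the call on the first gene cannot be separated from how reads were shared between them. How both Ensembl genes relate was not checked.

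**Figure D1:**
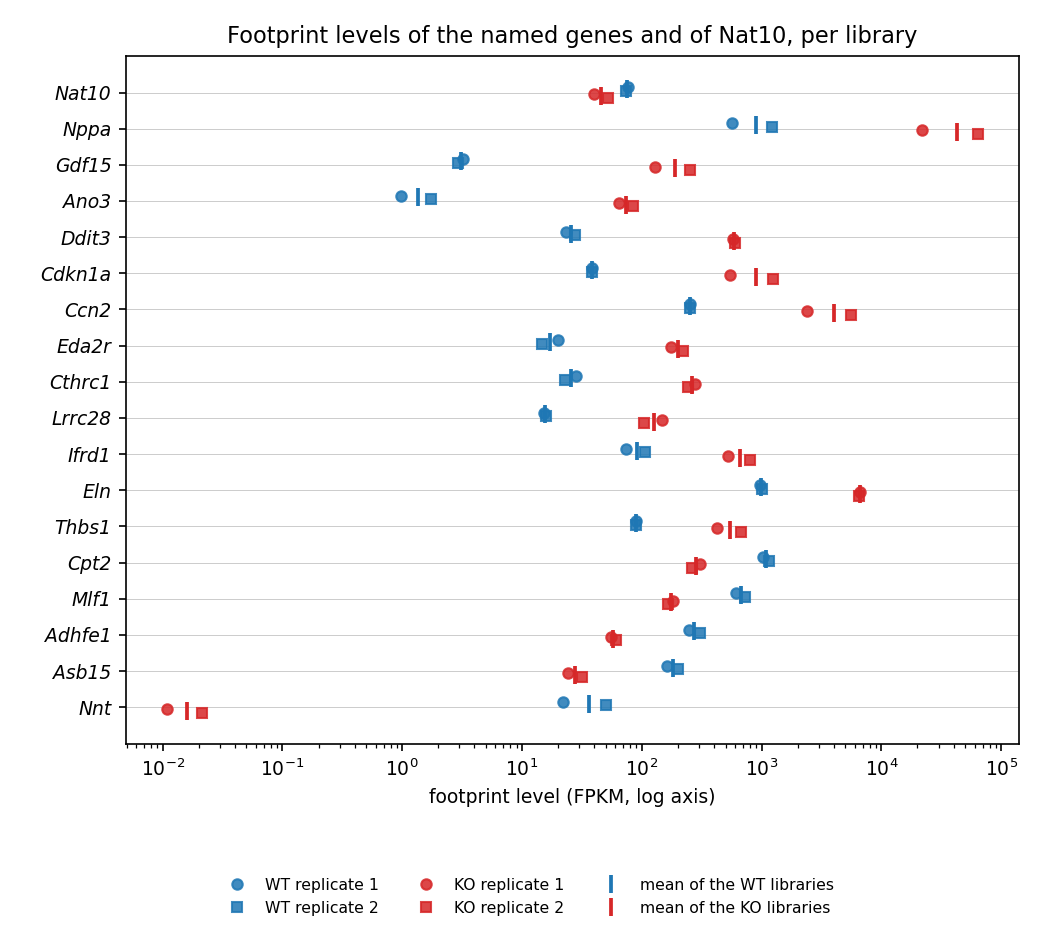
Footprint level in FPKM (log axis) of the named genes past the threshold and of Nat10, with 1 point per library and a tick at each group's mean of 2 libraries. The KO points of Nppa lie at 21973 and 63917 FPKM against 565 and 1223 in WT, and those of Cpt2 at 308 and 262 against 1020 and 1148.

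Across the 15031 tested genes, 38 rose and 19 fell by limma's test, and 2599 (17.3%) had an unadjusted p under 0.05. Of these 57 calls, 22 were named genes (17 higher, 5 lower), and 35 were small RNA genes, unnamed models or pseudogenes. In 32 of the 57 calls the gene was listed at 0 in both libraries of 1 group. More genes read higher than lower in KO: 10693 (71.1%) had a positive log2 change, with a median of 0.36, and median-ratio scaling brought that median to 0.0082. Gene list shifts are therefore given relative to the median of all tested genes. Members above or below the median of all genes are counted after that scaling, as a log2 change above or below 0. No gene passed when WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 was left out, with 0 rising and 0 falling in each case and 1010 to 2497 genes at an unadjusted p under 0.05. With median-ratio scaling the list members that rose were 2 of the fetal and stress list, 3 of the p53 targets, 2 of the integrated stress response and 4 of the matrix list, and those that fell were 1 of fatty acid oxidation and 2 of glycolysis. Leaving the small RNA genes and unnamed models out of the test gave 168 rising and 50 falling genes.

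Fetal and stress genes of the heart read higher as a list. Of 26 tested members, 3 rose over all genes (Ccn2, Nppa and Tagln, an actin-binding protein of smooth muscle) and none fell, while 11 rose adjusted over the list alone. The list's median lay 1.12 above that of all genes (log2, camera adjusted p = 0.00017; adjusted p = 0.479 with an estimated correlation). Ankrd1, a stress-responsive protein of cardiac muscle, read 1749 and 4118 FPKM in WT and 20829 and 28589 in KO (adjusted p = 0.081). Of 29 tested p53 targets, 2 rose over all genes (Cdkn1a and Eda2r), 21 rose adjusted over the list alone, and the median shift was 1.57 (camera adjusted p = 1.4e-08; adjusted p = 0.454 with an estimated correlation). Ddit4l, a regulator of mTOR signalling, and Phlda3, an inhibitor of Akt, read 10.4-fold and 5.95-fold higher without passing over all genes (adjusted p = 0.051 and 0.084). Of 30 members of the integrated stress response, 2 rose over all genes: Gdf15, and Ddit3 on 1 of its 2 Ensembl genes. Adjusted over the list alone 3 rose, with a shift of 0.61 (camera adjusted p = 0.00098, or 0.566 with an estimated correlation).

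Extracellular matrix genes read higher together with fibroblast markers. Of 42 matrix genes, 5 rose over all genes (Eln, Cthrc1, Ccn2, Thbs1 and Bgn, the proteoglycan biglycan), 40 rose adjusted over the list alone, and 41 of the 42 lay above the median of all genes. The shift was 1.17 (camera adjusted p = 3.4e-21; adjusted p = 0.454 with an estimated correlation). None of the 16 fibroblast markers passed over all genes and 14 rose adjusted over the list alone, with a shift of 0.79 (camera adjusted p = 2.3e-08; adjusted p = 0.454 with an estimated correlation). The 2 lists share 5 members. Col1a2, a chain of type I collagen, read 3372 and 2718 FPKM in WT and 9064 and 11841 in KO (adjusted p = 0.087). Tcf21, a fibroblast transcription factor, read 36.1 and 27.8 in WT and 107 and 185 in KO (adjusted p = 0.118). Macrophage markers (shift 0.47, camera adjusted p = 0.011), endothelial markers (shift 0.17, camera adjusted p = 0.029) and epicardial, glial and fat markers (shift 1.07, camera adjusted p = 0.046) also read higher, with no member past the threshold. With an estimated correlation their adjusted p was 0.67, 0.67 and 0.454.

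Energy metabolism and contractile genes read lower as lists. Of 32 fatty acid oxidation genes, 1 fell over all genes (Cpt2), 17 fell adjusted over the list alone, and 31 lay below the median of all genes, with a shift of -1.25 (camera adjusted p = 2.2e-26; adjusted p = 0.454 with an estimated correlation). Acaa2, a thiolase, and Hadh, a hydroxyacyl-CoA dehydrogenase, read 2.57-fold and 2.22-fold lower (adjusted p = 0.117 and 0.124). No member of the tricarboxylic acid cycle (23 genes, shift -0.98, camera adjusted p = 1.1e-16) or of nuclear-coded oxidative phosphorylation (75 genes, shift -0.76, camera adjusted p = 6.0e-23) passed, either over all genes or adjusted over the list alone. In the former 22 and in the latter 73 members lay below the median of all genes. Calcium handling and ion channel genes (30 genes, shift -0.96, camera adjusted p = 9.7e-11) had 4 members lower and 1 higher adjusted over the list alone. Kcnip2, a potassium channel subunit, read 4.21-fold lower (adjusted p = 0.131). Adult sarcomere genes (24 genes, shift -0.63, camera adjusted p = 1.1e-05) had 1 member lower adjusted over the list alone, Tcap, the titin cap protein, at 2.68-fold (adjusted p = 0.114 over all genes). With an estimated correlation the adjusted p of these 4 lists was 0.454 each. Glycolysis genes (24 genes, shift -0.56, camera adjusted p = 0.00038; adjusted p = 0.571 with an estimated correlation) included the glucose transporter Slc2a4 at 2.97-fold lower (adjusted p = 0.0595).

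Ribosome and translation genes read higher, with no member past the threshold over all genes. Of 67 cytosolic ribosomal protein genes, 36 rose and 1 fell adjusted over the list alone, with a shift of 0.75 (camera adjusted p = 4.7e-09; adjusted p = 0.454 with an estimated correlation). Rps19 and Rpl13a, of the small and the large subunit, read 4.55-fold and 2.63-fold higher (adjusted p = 0.088 for both), and reads of such genes may be shared with their pseudogenes. Ribosome biogenesis genes (65 genes, shift 0.41, camera adjusted p = 6.0e-06; adjusted p = 0.646 with an estimated correlation) had 56 members above the median of all genes. Translation factors (50 genes, shift 0.21, camera adjusted p = 0.0024; adjusted p = 0.67 with an estimated correlation) had 4 members higher adjusted over the list alone, among them Eef1b2, an elongation factor subunit, at 2.78-fold. Cell cycle genes (42 genes, shift 0.49, camera adjusted p = 0.0073) and replication-dependent histones (18 genes, shift 1.03, camera adjusted p = 0.0017) read higher, with adjusted p = 0.705 and 0.67 with an estimated correlation. Ccnd2, a D-type cyclin, read 3.20-fold higher (adjusted p = 0.088). Interferon response genes (30 genes, shift -0.59, camera adjusted p = 0.011) and erythroid markers (10 genes, shift -0.60, camera adjusted p = 0.033) read lower relative to all genes, with adjusted p = 0.67 for both with an estimated correlation.

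With the preset correlation, 13 lists stood above and 8 below the other genes, and 9 did not pass (adjusted p 0.052 to 0.884). None of the 21 held with an estimated correlation, which 2 libraries per group estimate poorly. Among the called lists, 9 also lost their call when a single library was left out. Without WT replicate 1 the adjusted p was 0.061 for endothelial, 0.865 for macrophage and 0.163 for epicardial, glial and fat markers. Without WT replicate 2 it was 0.781 for cell cycle, 0.191 for histones, 0.278 for interferon response, and 0.1295 for endothelial and for erythroid markers. Without KO replicate 1 it was 0.889 for cell cycle, 0.301 for histones, 0.108 for interferon response, 0.073 for glycolysis and 0.149 for epicardial, glial and fat markers. Without KO replicate 2 it was 0.135 for translation factors, 0.232 for endothelial, 0.175 for macrophage and 0.132 for erythroid markers.

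**Figure D2:**
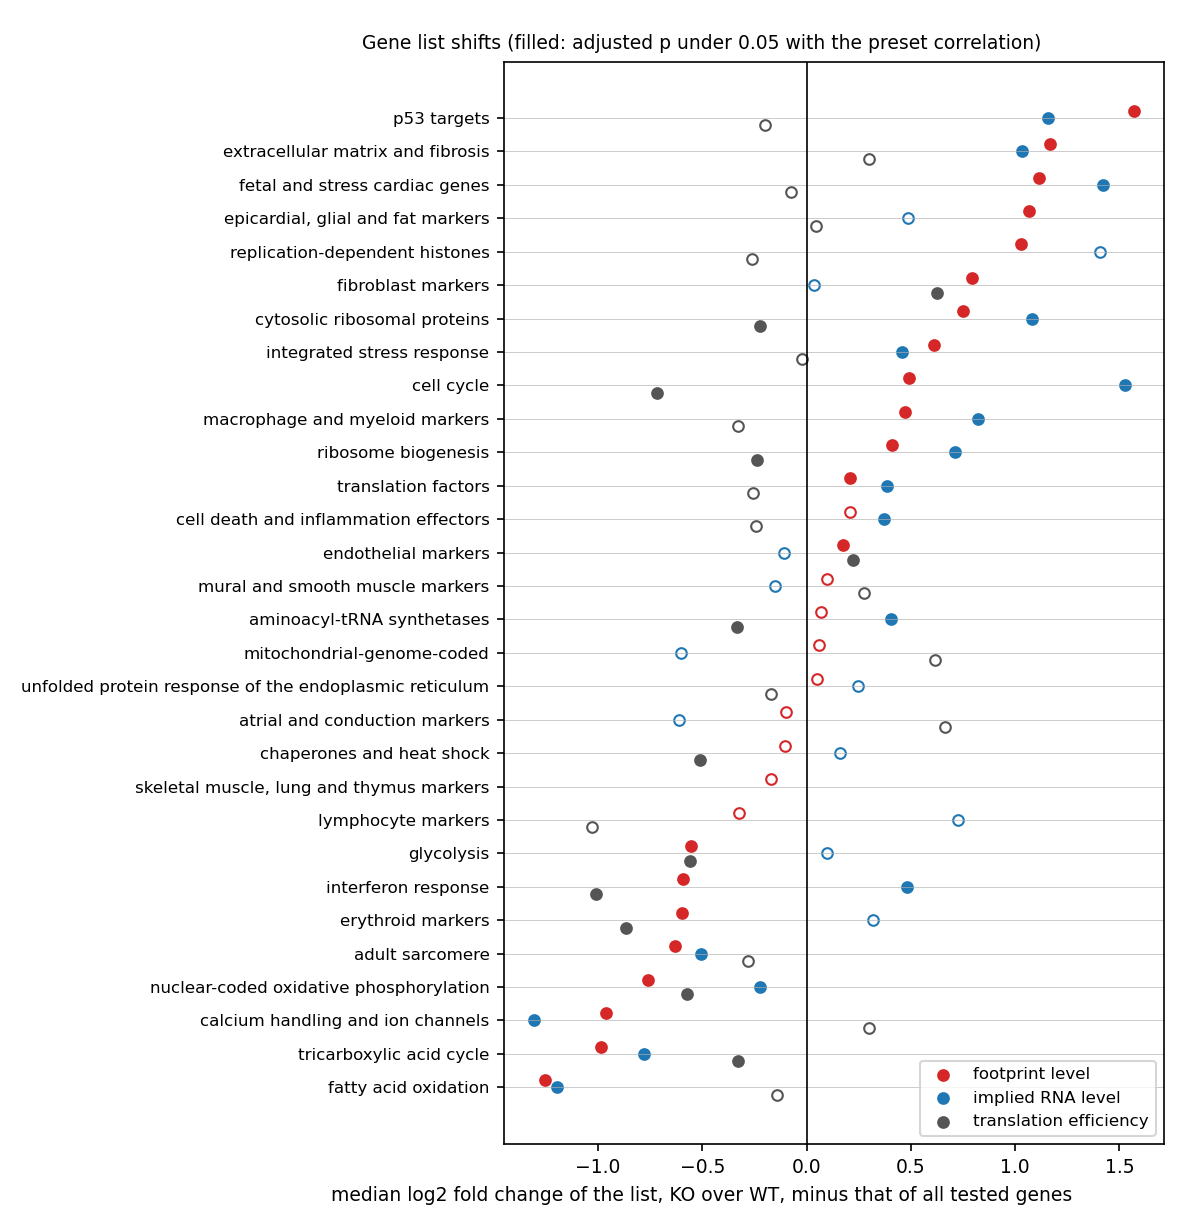
Median log2 fold change (KO over WT) of each gene list minus that of all tested genes, for the footprint level, the implied RNA level and TE, where filled points passed at an adjusted p of 0.05 with the preset correlation. Fatty acid oxidation lies at -1.25 for footprints and -1.20 for RNA, p53 targets at 1.57 and 1.16, and cell cycle at 0.49 for footprints, 1.53 for RNA and -0.72 for TE.

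The implied RNA level shows how far the footprint changes were already present in the RNA. Genes are named here by rule, among those with a mean footprint level of at least 5 FPKM in 1 group. Nppa rose 154-fold, from 48.3 ± 25.6 to 7312 ± 3494 FPKM (SD, n = 2, adjusted p = 0.012), Gdf15 112-fold (adjusted p = 0.020), Ano3 46.1-fold (adjusted p = 0.014) and Cdkn1a 20.3-fold (adjusted p = 0.012). Also among the 12 with the largest rise were Pmaip1, the pro-apoptotic protein NOXA, at 20.2-fold, Col12a1, a collagen, at 24.0-fold, Ass1, the urea-cycle enzyme argininosuccinate synthase, at 24.9-fold, and Serpina3n, a secreted protease inhibitor, at 19.8-fold (adjusted p = 0.019 to 0.046). Serpina3n did not pass without KO replicate 1 (adjusted p = 0.0763). Syt12 (a synaptotagmin), Aqp8 (a water channel), Cgref1 (a calcium-binding growth regulator) and Krt80 (a keratin) rose 58.8-, 41.1-, 30.7- and 26.2-fold. Their WT values were only 0.073 and 0.105 FPKM, 0.10 and 0.19, 0.18 and 0.18, and 0.32 and 0.24 in that order. Those of Ano3 were 0.089 and 0.054, and those of Pmaip1 0.22 and 0.11. No pseudocount was added to the RNA level and the floor was on footprints, so folds from such low values are uncertain. At the same footprint floor, the largest falls were those of Kcnj3, a potassium channel of the atria, at 68.8-fold lower, Slc36a2, an amino acid transporter, at 34.3-fold, Art1, a muscle ADP-ribosyltransferase, at 28.6-fold, and Pla2g5, a secreted phospholipase, at 22.4-fold (adjusted p = 0.014 to 0.043). The KO values of Kcnj3 were 0.036 and 0.62 FPKM and those of Slc36a2 0.072 and 0.74. Below these came, among others, Rp1, Asb15, Smco1, Klhl33, Rbfox1 (a splicing factor of muscle and brain), Phkg1 (the catalytic subunit of phosphorylase kinase) and Gal3st3, at 11.96- to 19.2-fold lower. Of these, Rp1 did not pass without WT replicate 2 (adjusted p = 0.0602).

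The size of several of these RNA changes rested on single libraries. Without KO replicate 1 the log2 change was -4.05 for Kcnj3 (-6.10 with all libraries), -3.42 for Slc36a2 (-5.10), -3.83 for Art1 (-4.84), -3.17 for Rp1 (-4.27), -3.09 for Asb15 (-4.19), -2.98 for Klhl33 (-3.95) and -2.92 for Gal3st3 (-3.58). Without KO replicate 2 the same 7 genes read -8.16, -6.78, -5.85, -5.37, -5.28, -4.92 and -4.24. For Gdf15 (6.80 with all libraries) it was 5.84 without KO replicate 1, 7.76 without KO replicate 2, 5.78 without WT replicate 1 and 7.82 without WT replicate 2, and for Serpina3n (4.31) 3.19, 5.43, 3.31 and 5.30 in that order. For Syt12 (5.88) it was 4.95 without KO replicate 1 and 6.81 without KO replicate 2. For Ass1 (4.64) and Col12a1 (4.58) it was 3.50 and 3.80 without WT replicate 1, and 5.78 and 5.37 without WT replicate 2.

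Of 12529 tested genes, 526 rose and 192 fell in the implied RNA level by limma's test, and 3544 (28.3%) had an unadjusted p under 0.05. The median log2 change was 0.22, and median-ratio scaling gave 327 rising and 309 falling genes, so the share of calls that were higher went from 73.3% to 51.4%. Leaving out WT replicate 2 gave 891 rising genes and leaving out KO replicate 2 gave 2632 rising and 1110 falling genes.

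RNA of proliferation, p53 and matrix genes rose in number. Of 41 cell cycle genes 25 rose over all genes, 36 adjusted over the list alone, and none fell (shift 1.53, camera adjusted p = 1.9e-14; adjusted p = 0.574 with an estimated correlation). Cdk1, the mitotic kinase, and Ccnb2, a B-type cyclin, rose 3.90-fold and 5.02-fold (adjusted p = 0.022 and 0.017). Of 28 p53 targets 16 rose and 1 fell over all genes, and 20 rose and 1 fell adjusted over the list alone (shift 1.16, camera adjusted p = 1.1e-09; adjusted p = 0.429 with an estimated correlation). Aen, an apoptosis-enhancing nuclease, rose 6.43-fold (adjusted p = 0.014). Of 42 matrix genes 17 rose over all genes, 34 adjusted over the list alone, and none fell (shift 1.03, camera adjusted p = 2.3e-12; adjusted p = 0.677 with an estimated correlation). Tnc, tenascin C, rose 8.69-fold and Tgfb2, a transforming growth factor, 6.46-fold (adjusted p = 0.014 and 0.016). Of 26 fetal and stress genes 10 rose over all genes, and 13 rose and 2 fell adjusted over the list alone (shift 1.42, camera adjusted p = 0.00041; adjusted p = 0.682 with an estimated correlation). Xirp2, an actin-binding repeat protein of striated muscle, rose 11.5-fold (adjusted p = 0.023). Fibroblast markers as a list did not pass in RNA (16 genes, shift 0.034, camera adjusted p = 0.311), while Tcf21 rose 3.19-fold and Vim, the intermediate filament vimentin, 2.64-fold (adjusted p = 0.029 and 0.047). Vim did not pass without WT replicate 1 or WT replicate 2 (adjusted p = 0.291 and 0.0542). With median-ratio scaling, 20 cell cycle genes, 14 p53 targets, 15 matrix genes, 10 fetal and stress genes and 1 fibroblast marker rose, and 1 p53 target and 1 fetal and stress gene fell.

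RNA of ribosome and translation genes also stood above the other genes. Among 58 cytosolic ribosomal protein genes 14 rose and 1 fell over all genes, and 55 rose and 1 fell adjusted over the list alone (shift 1.08, camera adjusted p = 1.9e-14; adjusted p = 0.677 with an estimated correlation). The member that fell was Rpl3l, the muscle paralogue of Rpl3, at 6.97-fold lower (adjusted p = 0.014), and Rps27l rose 4.23-fold (adjusted p = 0.026). Among 65 ribosome biogenesis genes 11 rose over all genes, 44 adjusted over the list alone, and none fell (shift 0.71, camera adjusted p = 4.1e-10; adjusted p = 0.677 with an estimated correlation). Rrp12 and Gar1, factors of ribosomal RNA processing, rose 5.63-fold and 3.60-fold (adjusted p = 0.019 and 0.033). Translation factors had 7 members that rose (50 genes, shift 0.39, camera adjusted p = 0.00023), and aminoacyl-tRNA synthetases none (22 genes, shift 0.41, camera adjusted p = 0.00072), with adjusted p = 0.682 and 0.677 with an estimated correlation. The integrated stress response had 8 members that rose and 2 that fell (27 genes, shift 0.46, camera adjusted p = 0.012; adjusted p = 0.682 with an estimated correlation). Psat1, of serine synthesis, rose 3.56-fold, and Chac1, a glutathione-degrading enzyme, was 9.89-fold lower (adjusted p = 0.031 and 0.023). Without KO replicate 1 the adjusted p of that list was 0.351. With median-ratio scaling, 10 ribosomal protein, 6 ribosome biogenesis, 3 translation factor and 7 integrated stress response genes rose, and 1 ribosomal protein and 2 integrated stress response genes fell.

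RNA of ion handling and fatty acid oxidation stood below the other genes. Calcium handling and ion channel genes had 8 members that fell and 1 that rose over all genes, and 15 and 1 adjusted over the list alone (30 genes, shift -1.31, camera adjusted p = 5.7e-12; adjusted p = 0.677 with an estimated correlation). Kcnd2, a potassium channel, was 33.8-fold lower, and Cacna1c, the cardiac L-type calcium channel, 3.05-fold lower (adjusted p = 0.027 and 0.031). Of 32 fatty acid oxidation genes 5 fell over all genes, 20 adjusted over the list alone, and none rose (shift -1.20, camera adjusted p = 8.7e-18; adjusted p = 0.677 with an estimated correlation). Cpt2 was 2.92-fold lower (adjusted p = 0.036). The tricarboxylic acid cycle had no member past the threshold (23 genes, shift -0.78, camera adjusted p = 4.6e-09; adjusted p = 0.429 with an estimated correlation). Adult sarcomere genes had 2 that fell, Tcap and Lmod2, an actin filament nucleator (24 genes, shift -0.51, camera adjusted p = 0.0021; adjusted p = 0.677 with an estimated correlation). The call of the list was lost without WT replicate 2 (adjusted p = 0.063) and without KO replicate 2 (adjusted p = 0.064). Tcap did not pass without WT replicate 2 (adjusted p = 0.0993), and Lmod2 not without WT replicate 1 or WT replicate 2 (adjusted p = 0.225 and 0.331). Oxidative phosphorylation passed as lower (75 genes, shift -0.22, camera adjusted p = 0.029; adjusted p = 0.757 with an estimated correlation) although its median log2 change was 0.00078. It did not pass without WT replicate 1, WT replicate 2 or KO replicate 2 (adjusted p = 0.122, 0.067 and 0.516). With the replicate block, the oxidative phosphorylation list and Lmod2 did not pass either (adjusted p = 0.067 by camera and 0.083 by limma). With median-ratio scaling, 11 ion handling, 9 fatty acid oxidation, 1 tricarboxylic acid cycle, 2 sarcomere and 2 oxidative phosphorylation genes fell. In that setting 1 ion handling gene rose.

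RNA of immune genes stood above the other genes. Macrophage markers had 4 members that rose over all genes and 12 adjusted over the list alone (19 genes, shift 0.82, camera adjusted p = 0.00018; adjusted p = 0.468 with an estimated correlation). Lgals3, galectin-3, rose 14.0-fold, and Ctss, a lysosomal protease, 3.24-fold (adjusted p = 0.033 and 0.022). Interferon response genes had 4 members that rose (27 genes, shift 0.48, camera adjusted p = 0.0076; adjusted p = 0.682 with an estimated correlation), among them Tap1, a peptide transporter of antigen presentation, at 3.701-fold (adjusted p = 0.029). Without KO replicate 2 the adjusted p of that list was 0.649. Cell death and inflammation effectors had 2 that rose, Hmox1, heme oxygenase, and Bcl2, an anti-apoptotic protein (27 genes, shift 0.37, camera adjusted p = 0.0068; adjusted p = 0.677 with an estimated correlation). Hmox1 did not pass without KO replicate 1, nor Bcl2 without WT replicate 1 (adjusted p = 0.0527 and 0.124). With median-ratio scaling, 3 macrophage markers, 2 interferon response genes and 1 cell death gene rose. With the preset correlation, 12 lists stood above and 5 below the other genes in RNA, and 12 did not pass (adjusted p 0.059 to 0.958).

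The TE comparison asks whether footprints per RNA differed between the groups. No single gene passed: limma called 0 of 12529 genes higher and 0 lower, with 759 (6.06%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.069. The median log2 change was 0.15. Among the genes with the smallest p and a higher TE in KO were Morn1, a MORN-repeat protein (0.90 ± 0.29 in WT and 12.1 ± 1.9 in KO, SD, n = 2), Insc (a spindle orientation adaptor), Ebf1 (a transcription factor), Bbs1 (a protein of cilia) and Dhx58 (an RNA helicase of antiviral signalling), with ratios of 13.6, 9.14, 13.5, 5.48 and 10.8 (adjusted p = 0.611 for each). Those with a lower TE were Nnt, Exo1, Kif2c, Ncf4, Ass1 and Aqp8. Nnt had a TE of 0.385 and 0.520 in WT and 0.00040 and 0.00045 in KO on ENSMUSG00000025453 (adjusted p = 0.069), with the caution on its Ensembl genes given above. For Exo1, an exonuclease of DNA repair, and Kif2c, a mitotic kinesin, TE was 7.86-fold and 7.14-fold lower (adjusted p = 0.611), with log2 footprint changes of 0.042 and -0.10 and log2 RNA changes of 3.04 and 2.73. Their WT RNA values were only 0.22 and 0.093 FPKM for Exo1 and 0.36 and 0.44 for Kif2c, so these ratios are uncertain. The RNA change of Exo1 did not pass limma's test (adjusted p = 0.056). Leaving out WT replicate 1 gave 23 higher and 10 lower genes, leaving out WT replicate 2 gave 6 and 2, and leaving out either KO library gave 0 and 0.

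TE of gene lists shifted without any member past the threshold over all genes. Members were counted as lower or higher in TE after median-ratio scaling, which left the median log2 change of all genes at -0.046. Nuclear-coded oxidative phosphorylation read lower in 71 of 75 members (shift -0.57, camera adjusted p = 2.1e-09). Interferon response genes read lower in 25 of 27 (shift -1.01, camera adjusted p = 3.5e-09) and cell cycle genes in 38 of 41 (shift -0.72, camera adjusted p = 6.3e-07). With an estimated correlation the adjusted p was 0.935 for each of these and for every other list called for TE. Ndufb5, a subunit of respiratory complex I, had a TE of 12.3 and 13.9 in WT and 6.64 and 7.15 in KO (adjusted p = 0.806). Isg15, a ubiquitin-like protein induced by interferon, had a TE of 17.5 and 22.5 in WT and 7.01 and 8.09 in KO (adjusted p = 0.785). Ccne1, a G1 cyclin, had a TE 3.75-fold lower (adjusted p = 0.676). Lower shifts were also called for erythroid markers (-0.87), glycolysis (-0.56), ribosome biogenesis (-0.24), the tricarboxylic acid cycle (-0.33), aminoacyl-tRNA synthetases (-0.34), chaperones (-0.51) and cytosolic ribosomal proteins (-0.22), at camera adjusted p of 0.00085, 0.0038, 0.012, 0.026, 0.026, 0.026 and 0.030. Markers of 2 cell types read higher by the same count: fibroblast markers in 15 of 16 genes (shift 0.63, camera adjusted p = 0.0027) and endothelial markers in 14 of 16 (shift 0.22, camera adjusted p = 0.030). Adjusted over the list alone, the histone H2bc9 passed.

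Most TE list calls rested on single libraries. Of the 12 lists called (2 higher, 10 lower), only oxidative phosphorylation held with every library left out in turn. Without WT replicate 1 the adjusted p was 0.698 for cell cycle, 0.114 for aminoacyl-tRNA synthetases, 0.114 for chaperones, 0.060 for ribosomal proteins and 0.202 for endothelial markers. Without WT replicate 2 it was 0.079 for interferon response and chaperones, 0.183 for glycolysis and ribosomal proteins, 0.1102 for ribosome biogenesis and aminoacyl-tRNA synthetases, 0.440 for the tricarboxylic acid cycle, 0.127 for endothelial and 0.0505 for fibroblast markers. Without KO replicate 1 it was 0.770 for glycolysis, 0.652 for ribosome biogenesis, 0.960 for aminoacyl-tRNA synthetases, 0.791 for chaperones and 0.797 for ribosomal proteins. Without KO replicate 2 it was 0.143 for cell cycle and for the tricarboxylic acid cycle, 0.082 for erythroid, 0.095 for fibroblast and 0.140 for endothelial markers. The replicate block ended the calls of aminoacyl-tRNA synthetases, chaperones, ribosomal proteins, the tricarboxylic acid cycle and endothelial markers (adjusted p = 0.083, 0.073, 0.083, 0.089 and 0.147).

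The footprint changes were set against the changes in TE and in RNA across the 12529 genes tested in all 3 measures. The log2 footprint change correlated with the log2 TE change at r = 0.46 (Spearman's rho = 0.49) and with the log2 RNA change at r = 0.55 (rho = 0.48). TE contains the footprint level, so part of the first correlation is built in, and the RNA level stands in its denominator, so RNA and TE changes correlated at r = -0.46. Without WT replicate 1 and without KO replicate 1 the first correlation was 0.62 and 0.68. Over the 718 genes called in RNA, a set chosen for large RNA changes, which raises this correlation, footprint and RNA changes correlated at r = 0.84. Over the same genes footprint and TE changes correlated at r = -0.17 and RNA and TE changes at r = -0.66. In 689 of the 718 (96.0%) the log2 changes of footprints and RNA had the same sign. Since most genes read higher in KO footprints, part of this agreement is built in. Set against the median footprint change, 479 of the 526 raised genes lay above it and 188 of the 192 lowered genes below it. Of the 21 genes called for footprints in this set, 18 were also called for RNA, all in the same direction: 14 of 16 higher and 4 of 5 lower. Independent lists of these sizes would share 0.67 higher and 0.077 lower genes. The genes Nppa, Gdf15, Ano3, Cdkn1a, Eln, Cpt2 and Asb15 were called in both.

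**Figure D3:**
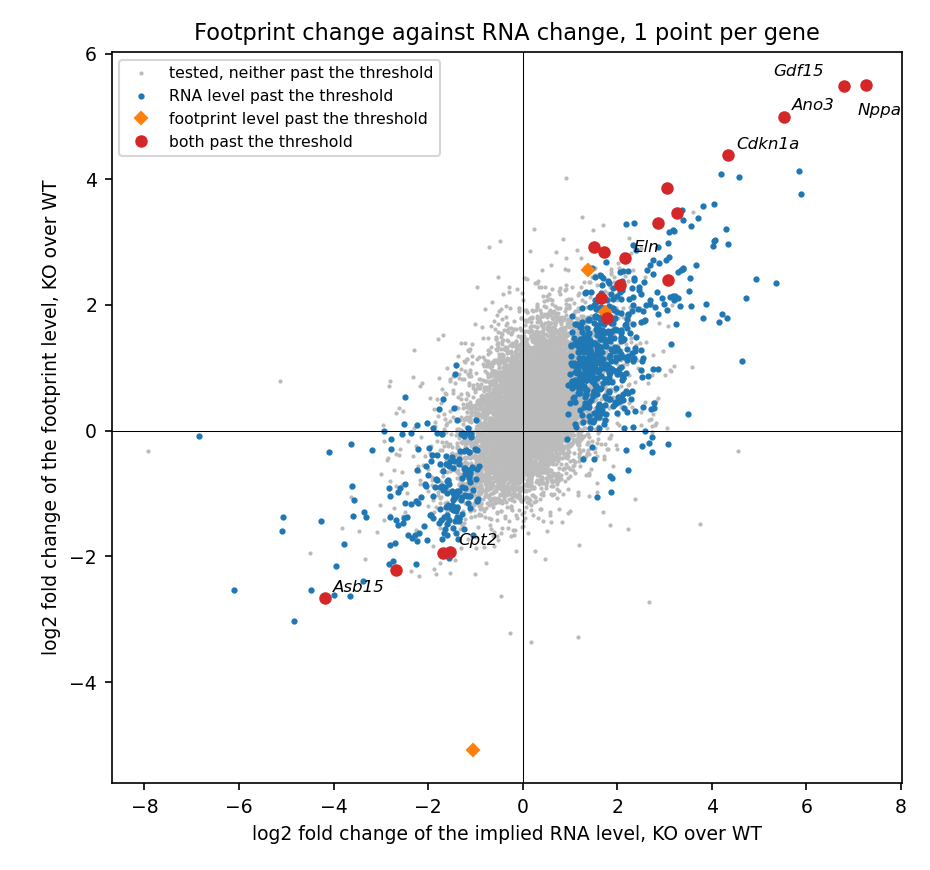
Log2 fold change (KO over WT) of the footprint level against that of the implied RNA level, 1 point per gene for 12529 genes, coloured by which of the 2 measures passed at an adjusted p of 0.05. The 18 genes called in both lie in the upper right and lower left, with Nppa at 7.26 for RNA and 5.49 for footprints and Asb15 at -4.19 and -2.66.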

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

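Chosen after the data were examined were leaving out small RNA genes, the floor on RNA values, leaving out symbols on more than 1 Ensembl gene, crossing the KO denominators, the TE pseudocount on the same genes, the crossed block, and the list alternatives for the implied RNA level. Unless stated, the cause of a difference was not tested.

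Footprint calls were 38 higher and 19 lower. They became 93 and 30 at a threshold of 0.1, 23 and 11 with a pseudocount of 0.1, 7 and 1 without a filter, 43 and 32 with median-ratio scaling, 309 and 104 with named genes rescaled, 168 and 50 with small RNA genes left out, 23 and 13 without a trend, 112 and 30 with robust variances, and 118 and 25 with the replicate block. Leaving out 1 library gave 0 to 0 higher and 0 to 0 lower genes; the lone library left is then assumed to vary like the other group, and fewer libraries alone lower the power. TE calls were 0 and 0. They became 0 higher and 1 lower at a threshold of 0.1, with a stricter filter and without a trend, 81 and 42 with a pseudocount of 0.01 that let in genes with a TE of 0 (15031 genes), 0 and 0 with that pseudocount on the 12529 genes alone, and 126 and 52 with the replicate block. Leaving out 1 library gave 0 to 23 higher and 0 to 10 lower. For implied RNA, 526 and 192 became 327 and 309 with median-ratio scaling, 1028 and 401 with the replicate block, and 2412 and 829 with a block that paired WT 1 with KO 2 and WT 2 with KO 1. Leaving out 1 library gave 482 to 2632 higher and 222 to 1110 lower. The numbers are not said to pair the libraries, and deviations of libraries with the same number correlated at -0.056 for footprints, -0.018 for TE and -0.22 for RNA.

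Lists called higher and lower were 13 and 8 for footprints, 2 and 10 for TE, and 12 and 5 for RNA. With an estimated correlation they were 0 and 0 in each. With fry, a rotation test, they were 0 and 0 for footprints, 1 and 0 for TE, and 4 and 1 for RNA, and the TE list was that of mitochondrial-genome-coded genes, tested by fry against no change and not against other genes. The replicate block gave 1 and 6 for TE. Leaving out 1 library gave 0 to 5 higher and 3 to 9 lower TE lists, and 3 to 6 lower RNA lists. Single lists changed sign when a library was left out, each short of the threshold on the other side. As -log10 p with the sign of the direction, their ranges were -0.12 to 10.1 for cell cycle footprints, -8.87 to 0.64 for interferon response footprints, -7.65 to 1.10 for erythroid footprints, -7.49 to 0.42 for ribosome biogenesis TE, and -8.70 to 0.32 for oxidative phosphorylation RNA.

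The correlation between footprint and TE changes ran from 0.38 to 0.68 when 1 library was left out. Nat10 kept its direction and stayed short of the threshold in every alternative run, with a log2 footprint change of -1.09 to -0.53. Of the tests of other named genes, 766 kept direction and side of the threshold, 185 kept direction only, and 0 changed direction. Nat10 and the genes named by rule in each comparison had both KO libraries on the same side of both WT libraries. Leaving out a library could therefore not turn their direction, so that part of the 0 was set by the choice of genes. Of the tests of single lists, 225 kept both, 103 direction only, and 5 changed direction. The footprint call of Nppa was lost with a pseudocount of 0.1, without a filter and without a trend (limma adjusted p = 0.077, 0.188 and 0.152). So were those of Cdkn1a, Ccn2, Lrrc28, Ifrd1, Thbs1, Tagln, Bgn, Cpt2, Mlf1, Adhfe1, Asb15 and Nnt. Eda2r, Cthrc1 and Eln lost theirs without a filter and without a trend, and Gdf15 and Ano3 without a filter. Ddit3 kept its call in these settings. Count-based models were not run, since FPKM keeps no counts. The self-test recovered 28% of footprint changes of 4-fold and 14% of TE changes of that size, so smaller changes were mostly not detectable with 2 libraries per group.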

Other observations

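Chosen after the data were examined were the genes near Nat10, the setting of RNA beside footprint changes of single genes, the list tests of the implied RNA level, the classes of genes at 0, and the tests of crossed names and of counting noise; the tests of abundant transcripts, of depth and of genes at 0 were planned before their results were seen.

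Protein genes of the mitochondrial genome were read as a list without a call. Their implied RNA level was lower in KO in 6 of 6 tested genes (shift -0.60, camera adjusted p = 0.059), and their TE was higher in 6 of 6 (shift 0.62, camera adjusted p = 0.078). Footprint levels lay near the median of all genes (8 genes, shift 0.058, camera adjusted p = 0.475). For mt-Nd5, a complex I subunit, footprints read 16982 and 17863 FPKM in WT and 19182 and 29407 in KO, and TE 0.67 and 0.88 in WT and 2.48 and 1.58 in KO. How RNA from mitochondria was captured in the RNA libraries is not given in the sources used here.

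Values of 4 genes that rose in implied RNA and had a lower TE are set side by side here. Kif2c and Ncf4, a subunit of the phagocyte oxidase, rose 6.62-fold and 6.34-fold in RNA (adjusted p = 0.025 and 0.031), with log2 footprint changes of -0.10 and -0.19. Their WT RNA values were also low, at 0.36 and 0.44 FPKM for Kif2c and 0.48 and 0.47 for Ncf4. Ass1 and Aqp8 rose 24.9-fold and 41.1-fold in RNA, from low WT values of 0.30 and 1.44 FPKM and of 0.10 and 0.19 FPKM. Their log2 footprint changes were 1.11 (adjusted p = 0.408) and 2.35 (adjusted p = 0.152). None of the 4 passed for TE or for footprints. Of 63 tested genes that start within 10 Mb of Nat10, 1 was called for footprints (Ano3), against 48 of 14295 elsewhere (Fisher's exact p = 0.194). For RNA 5 of 55 were called (Ano3, Cd44, Cd59a, Mpped2 and Rcn1), against 700 of 12280 (Fisher's exact p = 0.243).

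Lists without a call are given here by shift and camera adjusted p. For footprints these were aminoacyl-tRNA synthetases (0.067, 0.1104), unfolded protein response (0.051, 0.1104), cell death and inflammation (0.21, 0.209), chaperones (-0.10, 0.637), mural markers (0.097, 0.244), lymphocyte markers (-0.32, 0.104), atrial and conduction markers (-0.10, 0.884), and skeletal muscle, lung and thymus markers (-0.17, 0.052). For RNA they were glycolysis (0.098, 0.958), unfolded protein response (0.25, 0.172), histones (1.41, 0.198), chaperones (0.16, 0.082), endothelial (-0.11, 0.272), mural (-0.15, 0.439), lymphocyte (0.73, 0.198), erythroid (0.32, 0.198), atrial (-0.61, 0.066), and epicardial, glial and fat markers (0.49, 0.562). For TE the lists without a call had adjusted p from 0.078 to 0.995.

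After each library was centred on its median ratio, among the 206 of 526 genes that rose in RNA and had at least 20 FPKM of footprints in all 4 libraries, 85.44% read higher in KO replicate 1 than in KO replicate 2 by RNA (95% interval 79.9 to 89.9), while 59.22% read higher in KO replicate 2 by footprints (52.2 to 66.0). Counting noise that acts on each gene alone would leave both shares near an even split. The bound set for it, after the data were examined, was 40% to 60%. The RNA share lies outside that bound. The footprint share of 59.22% has an interval (52.2 to 66.0) that lies above an even split and reaches beyond the bound. By that bound, noise on the footprint side stays open. Among 108 of the 192 lowered genes, by the same limit, RNA read higher in KO replicate 1 in 13.9% and footprints higher in KO replicate 2 in 51.9% (42.03 to 61.57), which favours neither heart. If the names of the KO libraries were crossed between the kinds of library, the KO difference in footprints would run against that in RNA. Over these 314 genes the correlation was -0.164 (95% bootstrap interval -0.268 to -0.053). The interval resamples genes, which are not independent, within a single pair of libraries. Between the WT libraries the same correlation was 0.068, so no pair shows what matched names would give. With such weak values, matched names, crossed names and RNA taken from other hearts cannot be told apart. Whether the RNA came from the same hearts stays open and bears on every TE value.

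Most genes read higher in the KO footprint libraries, with a median log2 change of 0.377 over named genes. If the most abundant transcripts had fallen and set the scale, leaving them out would remove the difference. The top 20 named genes held 26.4% and 28.9% of the sum over named genes in WT and 22.7% and 23.1% in KO. They were left out and each library was rescaled on the remaining named genes, so small RNA genes and unnamed models left the scale too. The median was then 0.241 (0.15 to 0.322 over library pairs), so these 20 account for part of the difference at most. Rescaling on named genes in a separate run gave a median of 0.325, so the drop cannot be credited to the 20 genes alone. No other named genes were left out, so a fall over a wider set of abundant genes stays open. By mean FPKM the median was 0.438 at 1 to 10, 0.412 at 10 to 100 and 0.269 at 100 to 1000. It was -0.158 in the 272 genes from 1000 FPKM up, whose log2 ratio of sums was -0.113. Sampling depth does not move summed FPKM, so shallower KO libraries would leave the sums over weak genes level; the log2 ratio of the sums over 11516 genes of mean FPKM 1 to 100 was 0.391 (0.168 to 0.603 over pairs). A difference between genotypes in the spread of translation over genes stays open as an untested hypothesis, as does the authors' scaling.

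Some genes were listed at 0 in both libraries of 1 group and measured in both of the other. The split by genotype gave 292 such genes, 188 of them small RNA genes or unnamed models, against 229 and 200 in the other 2 splits of the 4 libraries. The genotype count was 1.275 times the higher of these, within the bound of 1.5 set beforehand for presence or absence by chance on genes with few reads. By class it was 1.12 for small RNA genes and unnamed models (188 against 168, 95% interval 0.90 to 1.39). For named genes it was 1.53 (104 against 68, 1.12 to 2.11). That interval lies above an equal count but spans the bound, so by that bound chance is left open for named genes. With 3 splits no share below 0.333 can be had, and a genotype effect on single genes among them stays untested.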
